A study of Rattus norvegicus with 6 samples.

How the data were processed

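Total RNA of rat alveolar tissue was isolated with TRIzol and made into single-end libraries with the Ion Total RNA-Seq Kit v2, per the labels' protocols. The authors deposited 1 table of whole-number counts per gene symbol for all 6 libraries, with no normalization, so far as its values show. The aligner, the counting program, the genome build, the annotation and the use of strand are not given in the sources used here. Reads of near-identical copies (globin, histone, ribosomal protein, protease, immunoglobulin and major histocompatibility genes, Hnrnpc and genes named LOC) and of overlapping genes could therefore have been split or shared, and their values are uncertain. Each column was matched to a library by its title. No coordinates are given, since the build is not stated; the RefSeq table of assembly GRCr8 was used only for names, and it matched 20208 of 37203 gene names as current symbols and 23050 when synonyms were added.

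Groups were taken from the titles (case, control) before the data were examined. The source field says the opposite of what these words would usually mean, no condition was inferred from values, and all differences are case minus control. Library totals ranged from 10886303 to 14433740 counts, at which a count of 0 allows up to 3 counts, or 0.2 to 0.274 CPM, for counting error alone. Of 37203 genes, 11182 had no count in any library.

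Genes were filtered with edgeR's filterByExpr, which left 16066, normalized with TMM (trimmed mean of M-values) and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. The design held the group alone and the Benjamini-Hochberg adjusted threshold was 0.05. CPM values are counts scaled to the TMM-adjusted library size, and log2 CPM was computed with a prior count of 2. The common biological coefficient of variation was 0.322. The log2 fold change had a median of -0.024 over all tested genes, and this median ranged up to 0.024 with other scalings.

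The 31 gene lists, 27 of symbols and 4 of name patterns, were fixed before the data were examined. They covered bone cells (osteoclast, osteoblast, osteocyte, osteoclastogenic signalling, Wnt, BMP and TGF-beta), inflammation and leukocytes (acute inflammation, interferon response, neutrophil and myeloid precursor, macrophage, T and NK cell, B and plasma cell), matrix (fibrillar matrix and ligament, matrix proteinases and inhibitors, cartilage) and vessels and nerve (endothelium, angiogenic and hypoxia signalling, nerve and Schwann cell). Others covered neighbouring tissues (skeletal muscle, glycolysis and muscle energy, oral epithelium, tooth-forming cell, salivary gland, adipocyte, erythroid) and cell state or RNA class (immediate early and heat shock, proliferation, ribosomal protein, mitochondrially encoded, small non-coding RNA, histone). After the gene names, but not their values, had been seen, 7 members were matched through older symbols. The 30 lists with at least 5 tested members were tested two-sided with camera of limma 3.58.1, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists.

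Genes were named by a rule set before the data were examined: those with the largest changes past the threshold with separate groups and a mean of at least 5 CPM or, where fewer than 5 passed in a direction, the 5 with the smallest p in that direction. Genes named LOC or RGD were skipped. The rule added up to 3 members of each list with the smallest p, and 18 bone and inflammation genes that are always given. It took 113 genes, of which 111 could be tested, and the text gives a part of them. Genes named outside the rule are said to be so where they appear.

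The test was first run on simulated counts for the same 16066 genes, libraries and spread, with 200 changed genes in each of 10 simulations. It called 11.5% of 2-fold, 66.9% of 4-fold and 88.7% of 8-fold changes, and 8.24% of its calls were false. Camera was run on the first simulation only, where it called the shifted list and 0 of 20 unchanged lists. The simulated genes varied independently of each other, whereas the correlation estimated within a list of the real data reached 0.94 (skeletal muscle). The simulation therefore cannot show how often camera, at the preset correlation, calls unchanged lists whose members move together. The shares of changes called also rest on independent genes and on 200 changed genes, and may not hold for the real libraries.

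The alternatives set in advance were the size factors of DESeq2, upper-quartile scaling and library totals in edgeR; no filter, or at least 10 counts in 3 libraries; DESeq2 1.42.0, limma-voom and robust empirical Bayes; other thresholds; leaving out tissue and RNA-class genes; leaving out each library; and the title number as a block. For lists they included camera with an estimated correlation and fry. Leaving out both libraries numbered 5, and the number 5 as a covariate, were chosen after seeing the data. Shares of counts have 95% Wilson intervals. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.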

Results

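RNA was sequenced from rat alveolar tissue, the tooth-bearing part of the jaw, to compare remodelling around teeth moved with and without corticision. Corticision is a surgical cut into the cortical bone, used to hasten orthodontic tooth movement. The 6 libraries fell into 2 groups of 3 by their titles: case 5, case 6 and case 9, and control 5, control 6 and control 10. The source field of the case libraries reads without corticision, and that of the control libraries reads with corticision. The titles and the source field thus point opposite ways in their usual sense, and which of them is right is left open. Groups are named here by title, and every difference is case minus control. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

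The tissue was rich in bone matrix transcripts. Col1a1, the alpha 1 chain of type I collagen, was the most abundant gene in every library, from 3.65% of counts in case 9 (95% Wilson interval 3.64 to 3.66%) to 7.43% in case 5 (7.41 to 7.44%). Markers of other tissues differed between single libraries, and those of tooth-forming cells set case 5 and control 5 apart. Genes of the oral epithelium list took 0.723% of the counts of control 5 (0.718 to 0.728%) and between 0.0037% (0.00337 to 0.00408%, control 10) and 0.00998% (0.00947 to 0.0105%, case 6) of those of the others. Skeletal muscle genes took 0.00396% in control 5 (0.0036 to 0.00435%) and between 0.0238% (0.0229 to 0.0246%, case 5) and 0.208% (0.205 to 0.21%, case 9) elsewhere. Erythroid genes took 0.207% in case 6 (0.204 to 0.209%) and between 0.774% (0.769 to 0.779%, case 9) and 2.39% (2.38 to 2.4%, control 5) elsewhere. The mean log2 CPM of the tooth-forming cell list was 3.72 in case 5, 3.89 in control 5 and between 1.19 (case 9) and 1.57 (control 6) elsewhere. The intervals cover counting error only.

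Library totals were 12599324, 14433740 and 11745453 counts in case 5, 6 and 9 and 10886303, 13727508 and 11311391 in control 5, 6 and 10. The mean total was higher in case by 951100 counts, with a two-sided exact permutation p of 0.5, where 3 libraries against 3 allow no p under 0.1. Of 37203 genes in the table, 20826 to 22360 had a count in a library. Spearman correlations of log2 CPM (counts scaled to library size) between libraries, taken across genes, which are not independent replicates, ranged from 0.939 to 0.975. The first principal component held 42.3% of the variance and set case 5 (-34.8) and control 5 (-77.2) apart from the other 4 libraries (24.9 to 30.7). The second held 18.7%, with scores of -5.81, 34.7 and 30.4 in case 5, 6 and 9 and 3.27, -16.1 and -46.4 in control 5, 6 and 10. Thus the largest difference among the libraries followed the number 5 and not the groups. The third component held 15.9% and set case 5 (-52.1) and control 5 (31.4) at opposite ends, with the other 4 libraries between -2.2 and 8.97.

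The question for single genes was which ones differed in expression between the case libraries (source field without corticision) and the control libraries (with corticision). The gene with the smallest p was Ccl9, a chemokine of the CC family, at 14.1 ± 0.480 CPM in case and 40.0 ± 7.36 CPM in control (SD, n = 3 in each group here and throughout), a log2 fold change of -1.51 (SE 0.18). Among genes with a mean of at least 5 CPM and a name other than LOC or RGD, the next smallest p on the side lower in case belonged to Hnrnpc, an RNA-binding protein of the nucleus (37.2 ± 2.95 against 68.2 ± 9.38 CPM). Next came Ier3, an immediate early response gene (17.1 ± 2.20 against 31.9 ± 2.68 CPM), Inhba, the activin A subunit (12.4 ± 1.35 against 23.8 ± 3.21 CPM), and Nxn, a thioredoxin-like redox protein (69.7 ± 0.969 against 105.8 ± 7.04 CPM). On the side higher in case, by the same rule, stood Tpsab1, a mast cell tryptase (15.3 ± 8.78 against 3.04 ± 1.34 CPM), and Mcpt1l1, named as a mast cell protease (21.7 ± 10.1 against 7.55 ± 1.09 CPM). With them stood Cd22, a B cell surface receptor (29.3 ± 8.67 against 13.2 ± 2.47 CPM), Zfp771, a zinc finger gene (22.7 ± 3.21 against 11.7 ± 2.03 CPM), and Rasgrp2, an activator of Rap GTPases (182.8 ± 14.9 against 117.6 ± 9.31 CPM). In each of these 10 genes the 3 case libraries lay outside the range of the 3 control libraries.

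None of these genes passed the test over all genes. The edgeR quasi-likelihood test called 0 of 16066 genes at the threshold of 0.05, with a smallest Benjamini-Hochberg adjusted p of 0.879 for Ccl9. At an unadjusted p under 0.05 it gave 666 genes, 302 higher and 364 lower in case, where 803 would be expected with no effect at all. This count rested on single libraries: it was 1566 without case 5 and 1215 without control 5, but 367 without case 6 and 401 without control 10. The groups lay apart in 1361 genes, 8.47% of those tested, where chance gives 10%. DESeq2 called 26 genes (13 higher and 13 lower in case) and limma-voom 0. Without control 5, edgeR called 2 genes, Rn5-8s and LOC103691734, both lower in case and named here after their values were seen; Rn5-8s had 1, 0 and 0 counts in case 5, 6 and 9 and 1, 636 and 276 in control 5, 6 and 10.

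**Figure D1:**
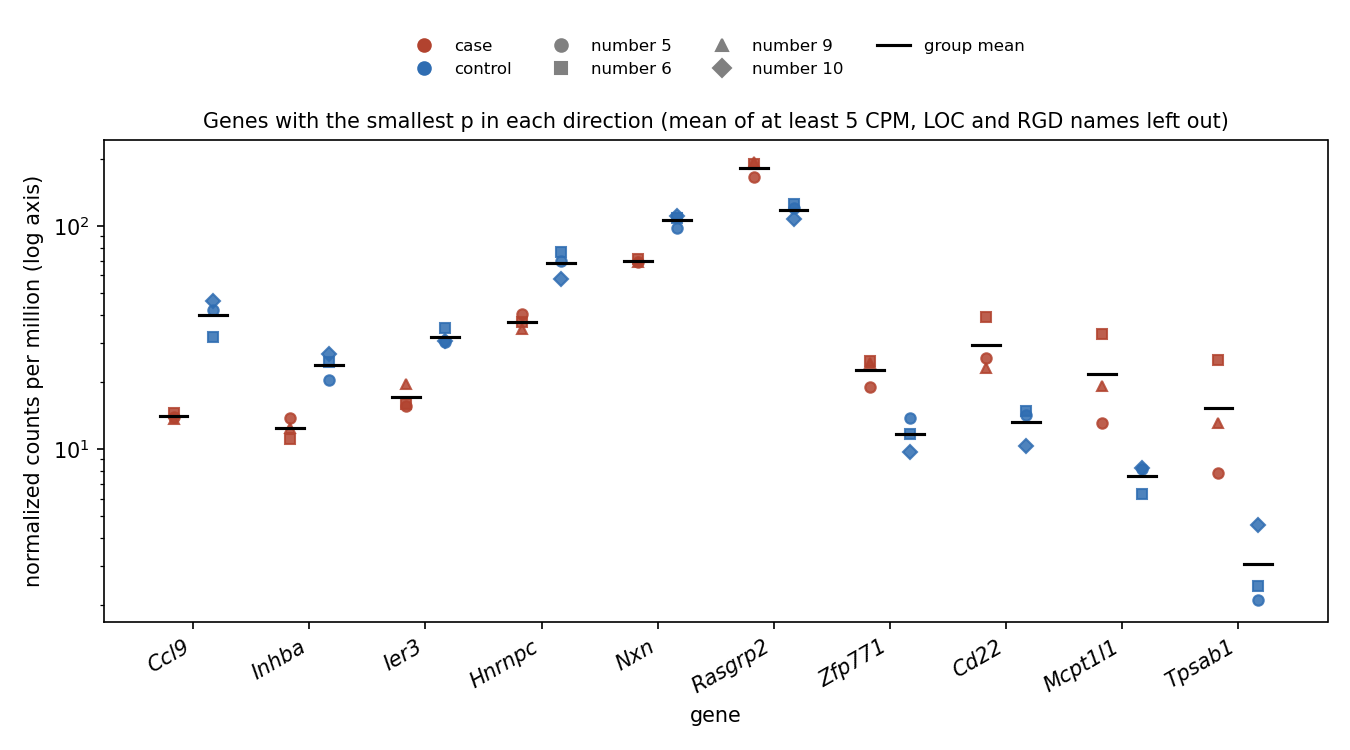
Normalized CPM (log axis) of the 5 genes with the smallest p in each direction among those with a mean of at least 5 CPM and a name other than LOC or RGD. Each point is 1 library, red for case and blue for control, its shape gives the title number, and bars are group means; for Ccl9 the means are 14.1 and 40.0 CPM, and none of the 10 genes passed the adjusted threshold.

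Gene lists fixed before the data were examined were compared with all other tested genes. Of 30 lists, 17 passed limma's camera test with a preset correlation of 0.01, of which 6 were higher and 11 lower in case. With a correlation estimated from the data 0 lists passed, the smallest Benjamini-Hochberg adjusted p in camera being 0.529. Splits of the 6 libraries that ignore the groups, run after these results were seen, gave 4 to 17 lists at the preset correlation. In every list 0 members passed over all genes. Adjusted over the list alone, 3 members of the osteoclastogenic signalling list, 3 of the acute inflammation list and 1 each of the erythroid, immediate early and heat shock, and bone morphogenetic protein (BMP) and transforming growth factor beta (TGF-beta) lists were lower in case. In the B and plasma cell list 1 was higher, and the other lists had 0. Of the 17 lists, 5 passed in the same direction whichever 1 of the 6 libraries was left out, and 12 did not. List medians are of log2 CPM differences.

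Cytokine and chemokine transcripts stood lower in the case libraries (source field without corticision) than in the control libraries (with corticision). All 18 tested members of the acute inflammation list had a negative fold change, with a median of -1.20. Il6, a cytokine of the acute phase, was at 0.273 ± 0.0914 CPM in case and 2.99 ± 1.41 in control, and the neutrophil-attracting chemokines Cxcl3 (1.30 ± 1.19 against 11.1 ± 4.81 CPM) and Cxcl6 (2.42 ± 0.907 against 8.95 ± 4.80 CPM) also had separate groups, as had 6 of the 18 in all. Il6 rested on few reads, with 4, 5 and 2 counts in case 5, 6 and 9 and 18, 38 and 48 in control 5, 6 and 10. Its case mean is near the CPM that a count of 0 allows. Cxcl3 had 1, 37 and 16 counts in case 5, 6 and 9. Il1b, which encodes interleukin 1 beta, overlapped between the groups at 36.3 ± 32.7 against 77.1 ± 68.9 CPM. The list passed camera with a Benjamini-Hochberg adjusted p of 2.08e-08 and had an adjusted p of 0.529 with an estimated correlation. It passed with each library left out in turn, with medians of -1.70 without case 9 to -0.80 without case 5 and -0.71 without control 6, while its mean log2 CPM in case 9 (2.51) lay above that in control 5 (2.15).

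A list of signals that promote or restrain osteoclast formation also stood lower in case (source field without corticision). Of 10 tested members of the osteoclastogenic signalling list, 7 had a negative fold change, and the median was -0.37. Csf1, the growth factor of macrophages and osteoclast precursors, was at 79.9 ± 12.8 CPM in case and 127.8 ± 18.5 in control, and Ptgs2, the inducible enzyme of prostaglandin synthesis, at 1.81 ± 1.13 and 5.97 ± 2.32. Tnfrsf11b, the decoy receptor osteoprotegerin, was at 22.3 ± 5.11 and 26.3 ± 1.93 CPM. The negative members thus include genes of both kinds, since Tnfrsf11b (log2 fold change -0.24) and Sema3a (-0.49) restrain osteoclast formation, as does Lgr4 (0.24) among the positive ones. Camera gave a Benjamini-Hochberg adjusted p of 0.00372, and an adjusted p of 0.529 with an estimated correlation. The rotation test fry, which asks whether members move one way on balance, gave a Benjamini-Hochberg adjusted p of 0.0358 for this list and called 0 of the others. The median was -0.54 without control 5 and -0.26 without control 6 or control 10. Il1b (log2 fold change -1.09), Il6 (-3.4) and Ptgs2 (-1.72) stand on this list and on the acute inflammation list, and are its most negative members. The others ran from -0.68 (Csf1) to 0.75 (Cxcl12), with Il34 (-0.29) also negative and Cx3cl1 (0.29) also positive. The list without the shared genes was not tested, so it does not show a shift apart from that of the acute inflammation list. Tnfsf11, which encodes the osteoclast differentiation factor RANKL, was listed at 0 in all 6 libraries, which for counting error alone allows up to 0.2 CPM in case 6 and 0.274 CPM in control 10. Hprt1, a gene every cell uses, was at 0, 118 and 71 counts in case 5, 6 and 9 and at 0, 0 and 1 in control 5, 6 and 10, so a listed 0 sets no bound on expression here. Tnf was too low to test, with 0, 1 and 2 counts in case 5, 6 and 9 and 3, 13 and 4 in control 5, 6 and 10.

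**Figure D2:**
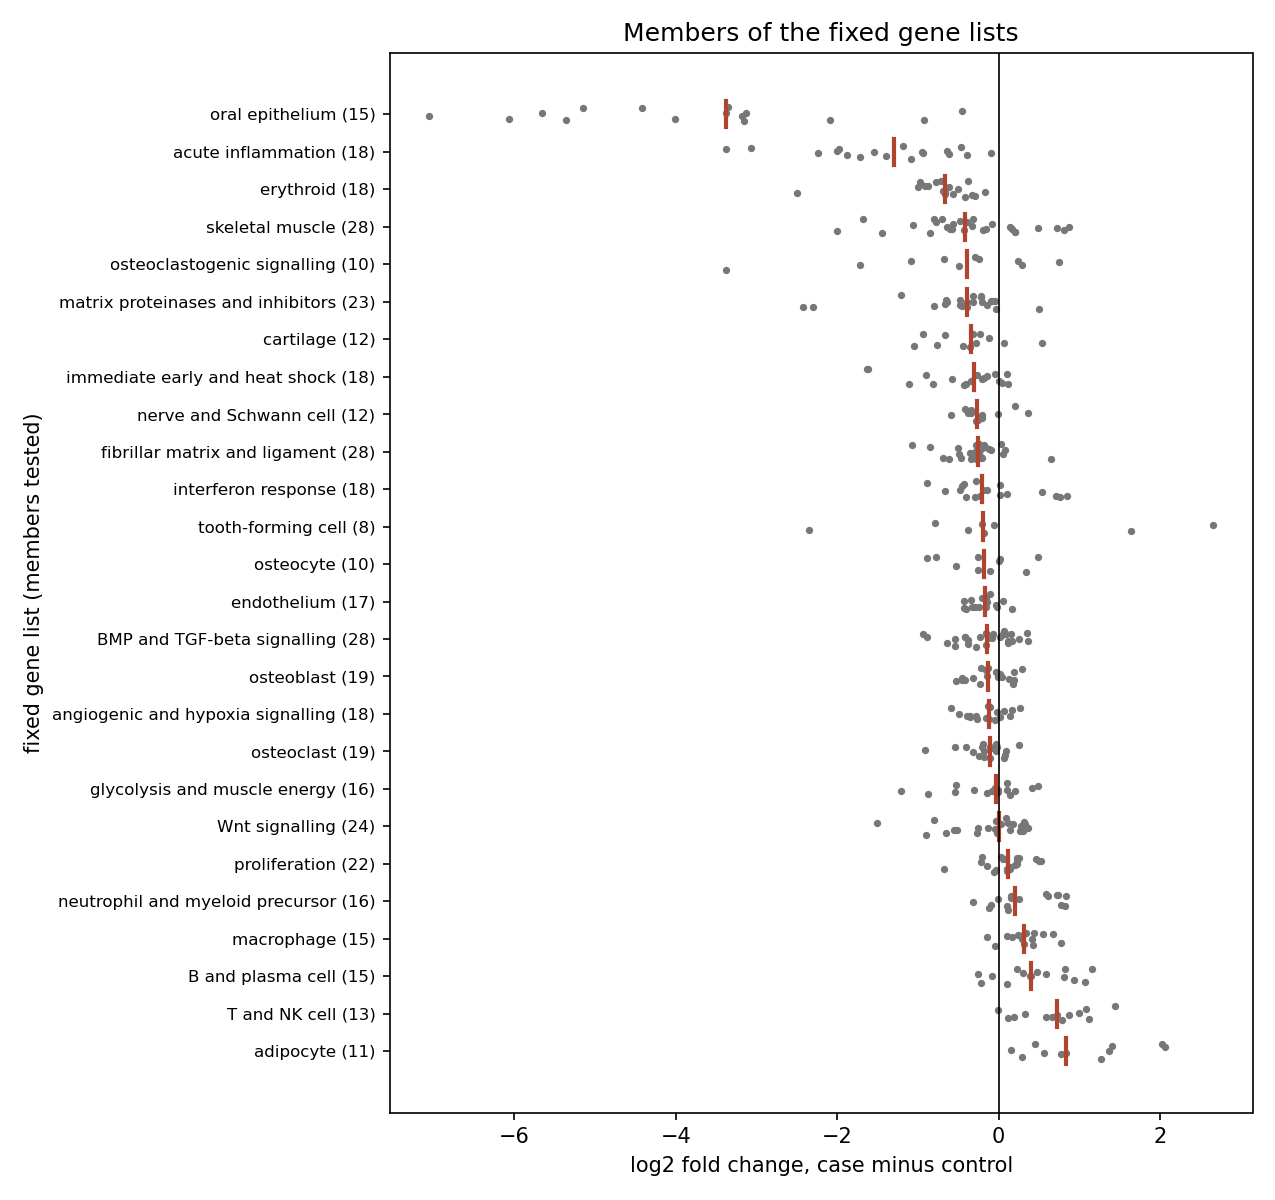
Fitted log2 fold change, case minus control, of the tested members of each symbol list with at least 5 tested members. Each grey point is 1 gene, red bars are medians over members, the number of members tested is in parentheses, and the vertical line marks 0; all 18 acute inflammation genes lie to its left.

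No list of the cells that resorb and build bone passed between case (source field without corticision) and control (with corticision), which does not show that the groups were alike. The osteoclast list had 15 of 19 members with a negative fold change, a median of -0.18 and a camera Benjamini-Hochberg adjusted p of 0.0796. The endothelium list, described below, passed with a similar median (-0.19) and 15 of 17 members negative. With an estimated correlation the unadjusted camera p was 0.105 for the osteoclast list and 0.149 for the endothelium list. The threshold thus sets these lists apart more than their values do. Among its genes, the proton pump subunit Atp6v0d2 was at 47.6 ± 1.91 and 69.5 ± 14.3 CPM, the phosphatase Acp5 at 1695 ± 296 and 1944 ± 326, the protease Ctsk at 2231 ± 598 and 2951 ± 1225, and Mmp9 at 1353 ± 148 and 1453 ± 370. The osteoblast list had 12 of 19 negative members, a median of -0.16 and a camera Benjamini-Hochberg adjusted p of 0.321. Spp1, which encodes osteopontin, was at 3644 ± 128 CPM in case and 4981 ± 490 in control with separate groups. Values of Col1a1 (49830 ± 21620 against 55070 ± 10780), Bglap (3907 ± 1848 against 3853 ± 946), Ibsp (2266 ± 328 against 2827 ± 884), Runx2 (80.3 ± 19.5 against 88.2 ± 6.38) and Sp7 (80.8 ± 42.2 against 70.7 ± 26.5) overlapped. The osteocyte list had a median of -0.15 and a camera Benjamini-Hochberg adjusted p of 0.365; its Wnt inhibitor Sost was at 182.5 ± 24.6 and 130 ± 79.5 CPM and Pdpn at 75.8 ± 18.3 and 129.8 ± 24.4. The tooth-forming cell list (6 of 8 negative, median -0.18), the cartilage list (10 of 12, median -0.37), the Wnt signalling list (12 of 24, median -0.03) and the BMP and TGF-beta signalling list (17 of 28, median -0.14) had camera Benjamini-Hochberg adjusted p of 0.286, 0.0796, 0.4 and 0.0796.

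The direction and the call of several of these bone lists depended on 1 library. Without case 5 the lists of osteoblast (median -0.39), osteocyte (-0.31), tooth-forming cell (-0.57), cartilage (-0.63), Wnt (-0.30) and BMP and TGF-beta genes (-0.30) passed as lower in case (source field without corticision). Without control 10 or control 6 the cartilage (-0.46 and -0.56) and BMP and TGF-beta lists (-0.12 and -0.15) passed. So did the osteocyte list without control 10 (-0.29), the tooth-forming cell list without control 6 (-0.42) and the osteoclast list without case 6 (-0.13), whose median was -0.08 without case 9 or control 10. The cartilage median was -0.11 without case 6, and that of the BMP and TGF-beta list -0.05 without control 5 and -0.07 without case 9. Other fits turned medians positive with no call: those of the osteocyte (0.11) and tooth-forming cell lists (0.40) without control 5, of the osteoblast (0.0090), tooth-forming cell (0.19) and Wnt lists (0.12) without case 9, of the tooth-forming cell (0.03) and Wnt lists (0.0043) without case 6, and of the Wnt list without control 5 (0.03) or scaled by library totals (0.01).

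Genes of the fibrous matrix and of its turnover stood lower in case (source field without corticision) than in control (with corticision). Of the matrix proteinases and inhibitors, 22 of 23 had a negative fold change with a median of -0.40. The metalloproteinases Mmp12 (1.98 ± 0.332 against 9.73 ± 6.85 CPM) and Mmp3 (1.29 ± 0.563 against 6.97 ± 5.80 CPM) and the aggrecan-cleaving protease Adamts1 (24.5 ± 2.92 against 56.6 ± 25.0 CPM) had the smallest p in the list, while the collagenase Mmp13 was at 1952 ± 658 and 2686 ± 1207 CPM. Camera gave a Benjamini-Hochberg adjusted p of 3.46e-05, and an adjusted p of 0.529 with an estimated correlation. Of the fibrillar matrix and ligament genes, 24 of 28 had a negative fold change with a median of -0.29, among them Postn, which encodes the ligament protein periostin (1404 ± 765 against 1941 ± 602 CPM), and the collagen cross-linking enzyme Lox (126 ± 37.6 against 204 ± 58.1 CPM). Their camera Benjamini-Hochberg adjusted p was 0.000159, and the adjusted p was 0.579 with an estimated correlation. Both lists passed with each library left out in turn, with medians of -0.41 without case 5 to -0.22 without case 9 and -0.19 without control 10 for the proteinases, and of -0.50, -0.19 and -0.12 without the same libraries for the fibrillar genes. The mean log2 CPM of the proteinase list was 5.82 to 5.91 in case and 6.11 to 6.61 in control, while for the fibrillar list case 5 (8.70) lay above control 5 (8.46) and control 6 (8.36).

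Vessel and nerve markers stood slightly lower on average in case (source field without corticision), with libraries that overlapped. In mean log2 CPM of the endothelium list, case 5 (6.03) lay above control 5 (5.98) and control 6 (6.02). For the nerve and Schwann cell list case 9 (4.45) lay above control 10 (4.35). Of the endothelium list 15 of 17 genes had a negative fold change with a median of -0.19, such as the junction gene Pecam1 (77.8 ± 2.69 against 102.9 ± 12.6 CPM), and of the nerve and Schwann cell list 10 of 12 with a median of -0.26. Camera gave Benjamini-Hochberg adjusted p of 0.00483 and 0.044, and adjusted p of 0.54 for both with an estimated correlation. The endothelium list did not pass without case 9 (median -0.10, and -0.11 without control 10 and -0.29 without case 5), nor the nerve list without case 5 (-0.23), case 6 (-0.18), control 5 (-0.30) or control 6 (-0.08). In the angiogenic and hypoxia signalling list 13 of 18 members were negative, with a median of -0.13 and Vegfa at 86.8 ± 4.84 against 110.8 ± 17.4 CPM. It had a camera Benjamini-Hochberg adjusted p of 0.0796 and passed without control 10 (-0.14), while its median was -0.02 without control 6 and -0.07 without case 5.

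Leukocyte marker lists stood higher on average in the case libraries (source field without corticision) than in the control libraries (with corticision), with libraries that overlapped. The mean log2 CPM of case 5 lay below those of control 6 and control 10 for the T and NK cell (2.69 against 3.43 and 2.80), macrophage (6.69 against 7.26 and 6.97) and neutrophil lists (8.44 against 9.23 and 8.63). In the neutrophil list case 6 (9.12) also lay below control 6 (9.23). For the B and plasma cell list case 6 (3.32) and case 9 (3.89) lay below control 5 (4.02) and control 6 (4.16). Positive fold changes were found for 12 of 13 T and NK cell genes (median 0.72), 12 of 15 B and plasma cell genes (0.46), 13 of 15 macrophage genes (0.29) and 12 of 16 neutrophil and myeloid precursor genes (0.23). Examples are the T cell receptor chain Cd247 (5.45 ± 3.09 against 2.50 ± 0.957 CPM), the B cell gene Ms4a1 (16.7 ± 2.86 against 8.73 ± 4.01 CPM), the scavenger receptor Cd163 (65.8 ± 31.9 against 38.5 ± 5.75 CPM) and Mpo, the peroxidase of neutrophil granules (2051 ± 579 against 1151 ± 327 CPM). Mpo had the largest fold change of its list (log2 0.83). The 4 negative members of that list were S100a9 (-0.12), Camp (-0.31), Ngp (-0.10) and Lcn2 (-0.0078), and S100a8 was at 0.10. The list holds precursor genes too, so it does not show that mature neutrophils were more numerous in case. In camera the Benjamini-Hochberg adjusted p were 0.000287, 0.00274, 0.00571 and 0.00412, and with an estimated correlation the adjusted p were 0.579, 0.54, 0.579 and 0.58. The T and NK cell list did not pass without case 6 (median 0.51, and 0.31 and 0.27 without case 9 and control 5), nor the B and plasma cell list without case 5 (0.46) or control 10 (0.08). The macrophage list did not pass without case 6 (0.18), case 9 (0.09) or control 5 (0.08), nor the neutrophil list without case 9 (0.11) or control 5 (0.14). Medians were larger without case 5 for the T and NK cell (1.11), macrophage (0.59) and neutrophil lists (0.59). They were also larger without control 6 for the macrophage (0.53), neutrophil (0.58) and B and plasma cell lists (0.79). The B and plasma cell list was at 0.79 without case 6 and 0.27 without control 5. The interferon response list had 11 of 18 negative members, a median of -0.19 and a camera Benjamini-Hochberg adjusted p of 0.0868. It passed as lower without case 9 (-0.25), while its median was -0.11 without control 6 and -0.13 without control 10.

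**Figure D3:**
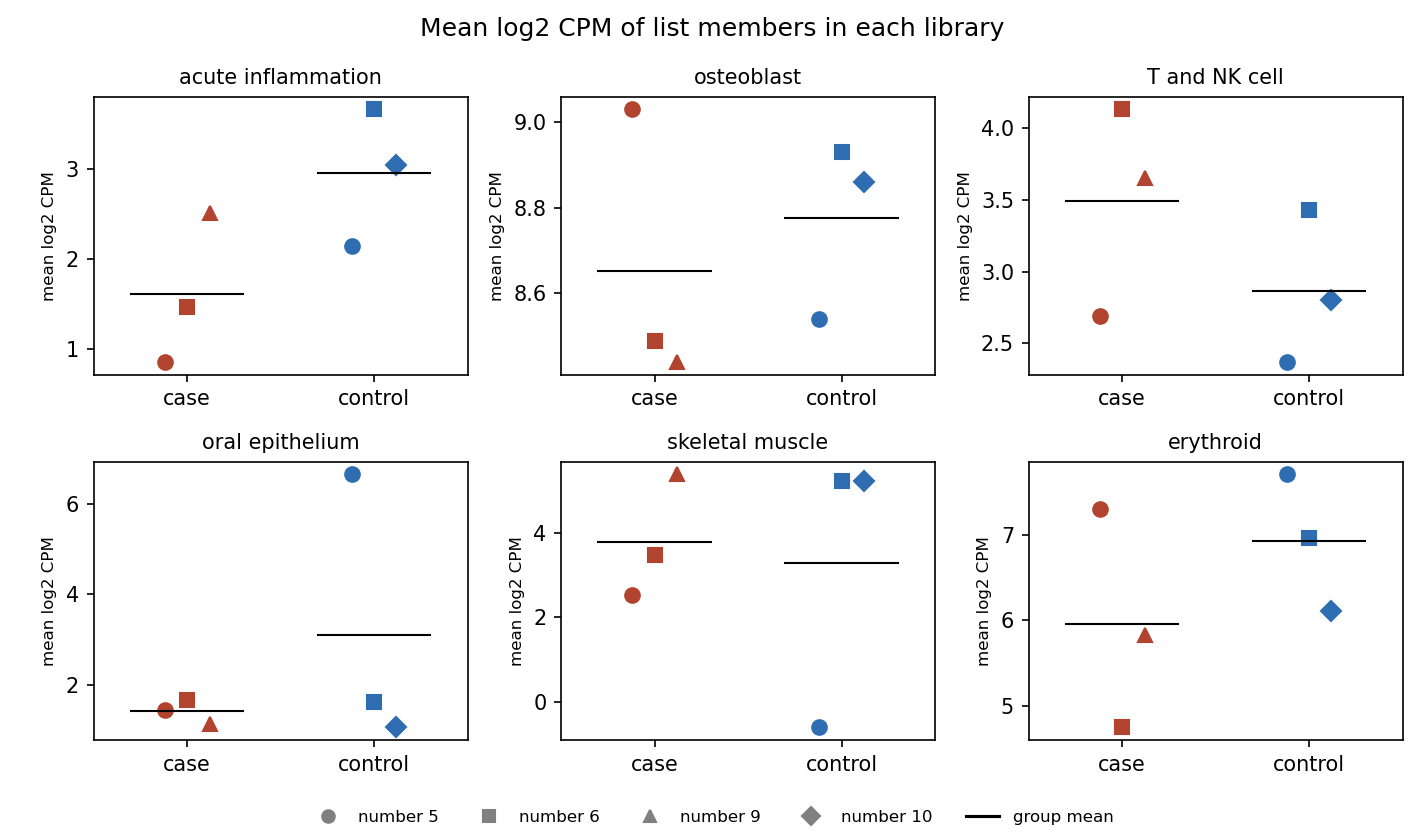
Mean log2 CPM of the tested members of 6 gene lists in each library. Each point is 1 library, red for case and blue for control, its shape gives the title number, and bars are group means; control 5 stands apart for oral epithelium and skeletal muscle genes, and case 9 (2.51) lies above control 5 (2.15) for acute inflammation.

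Markers of neighbouring tissues differed between case (source field without corticision) and control, with calls that rested on single libraries. All 11 adipocyte genes had a positive fold change (median 0.75), with Plin1, a lipid droplet coat gene, at 16.6 ± 19.0 against 4.11 ± 1.36 CPM and Pck1 at 15.5 ± 18.7 against 3.71 ± 1.17 CPM. All 18 erythroid genes had a negative one (median -0.80), with the beta globin gene Hbb-b1 at 104.1 ± 71.8 against 591 ± 178 CPM, a value made uncertain by near-identical globin copies. All 15 oral epithelium genes also had a negative one (median -1.61), with the keratin gene Krt13 at 1.01 ± 0.328 against 136 ± 232 CPM. Camera gave Benjamini-Hochberg adjusted p of 0.000256, 0.000159 and 0.000159, and the adjusted p was 0.579 for all 3 with an estimated correlation. The adipocyte list did not pass without case 6 (0.20) or control 5 (0.40), nor the erythroid list without case 6 (-0.24) or control 5 (-0.40), while the erythroid median was -1.52 without case 5 and -1.22 without control 10. Without control 5 the oral epithelium list turned to 0.14, and without control 10 it was at -2.90.

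The skeletal muscle list gave opposite signs by scale, with a median of 0.46 in log2 CPM but -0.41 in fitted fold changes, where 20 of 28 members were negative. Its camera Benjamini-Hochberg adjusted p was 0.14; it passed as higher in case without case 5 (1.07), control 6 (1.49) or control 10 (1.57) and as lower without control 5 (-1.49). The glycolysis and muscle energy list had 10 of 16 negative members, a median of -0.07 although camera pointed up, and a camera Benjamini-Hochberg adjusted p of 0.997. Only 2 salivary gland genes could be tested, Aqp5 (1.29 ± 0.447 against 1.08 ± 1.03 CPM) and Pip (1.07 ± 0.182 against 8.36 ± 12.8 CPM), too few for a list test. Median log2 CPM differences and median fitted fold changes also differed in sign for the Wnt (-0.03 and 0.0025), histone (0.06 and -0.04) and small non-coding RNA lists (0.04 and -0.0095), and the tooth-forming list had a mean fold change of 0.04.

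Cell division genes stood slightly higher in case (source field without corticision), and stress response and mitochondrially encoded genes lower. In the proliferation list 16 of 22 genes had a positive fold change (median 0.11), such as Birc5, a regulator of mitosis (19.9 ± 2.51 against 14.1 ± 1.83 CPM), and the DNA replication helicase subunit Mcm5 (100.1 ± 5.63 against 72.3 ± 14.6 CPM). In the immediate early and heat shock list 14 of 18 had a negative one (median -0.26), such as the stress-induced transcription factor Atf3 (2.86 ± 1.54 against 8.84 ± 2.27 CPM). Of the mitochondrially encoded genes 12 of 13 had a negative one (median -0.44), with ND4 at 505 ± 158 against 739.5 ± 76.8 CPM, and of the ribosomal protein genes, whose pseudogene copies make their counts uncertain, 69 of 95 (median -0.16). In camera these 4 lists had Benjamini-Hochberg adjusted p of 0.044, 0.000588, 3.46e-05 and 0.044, and with an estimated correlation the adjusted p were 0.689, 0.54, 0.54 and 0.824. The mitochondrial list passed with each library left out in turn (-0.52 to -0.31), but in mean log2 CPM case 9 (10.3) lay above control 6 (10.2). In the proliferation list case 6 (5.44) lay below control 5 (5.69) and control 6 (5.62). In the ribosomal list case 6 (6.43) lay above control 5 (5.8). The immediate early and heat shock list did not overlap, at 4.15 to 4.49 in case and 4.55 to 5.19 in control. The proliferation list did not pass without case 5 (0.11), case 9 (0.06) or control 10 (0.01), the immediate early list without control 5 (-0.13), or the ribosomal list without case 5 (0.07), control 6 (0.03) or control 10 (0.05). Larger medians were those of the proliferation list without case 6 (0.24) or control 5 (0.23), the immediate early list without case 6 (-0.41) or control 6 (-0.47), and the ribosomal list without case 6 (-0.28) or control 5 (-0.38). The small non-coding RNA and histone lists, with medians of 0.04 and 0.06, had camera Benjamini-Hochberg adjusted p of 0.997 and 0.617; the histone list passed as higher without case 6 (0.24) or control 5 (0.33).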

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

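Of the tests named here, leaving out both libraries numbered 5 and using the number 5 as a covariate were chosen after seeing the data. The count of genes past the threshold was 0 in edgeR under each scaling, filter and threshold tried, with limma-voom, robust empirical Bayes, tissue genes left out, both number 5 libraries left out and the number 5 as a covariate. DESeq2 gave 26 (13 higher and 13 lower in case), and leaving out 1 library in turn gave 0 to 2 (0 higher, and 0 to 2 lower, the 2 without control 5); the cause was not tested. Genes at an unadjusted p under 0.05, 666 with all libraries, numbered 1566, 367 and 473 without case 5, 6 and 9, 1215, 695 and 401 without control 5, 6 and 10, and 2294 without both libraries numbered 5. Of the 17 lists past the threshold, camera with an estimated correlation left 0 and fry 1, both by construction allowing for members that move together. The count of lists was 12 to 20 with 1 library left out, 16 without both number 5 libraries or with the covariate, 18 with library totals and 17 with DESeq2 size factors. Without both number 5 libraries B and plasma cell (0.50), oral epithelium (-0.016), nerve (-0.25) and immediate early genes (-0.015) lost their calls, while osteoblast (-0.41), cartilage (-0.49) and skeletal muscle genes passed as lower; with the covariate nerve and proliferation genes lost theirs and cartilage genes passed. With 1 library left out, lists called with or without that library whose medians changed sign were skeletal muscle (-1.49 without control 5, up to 1.57 without control 10), oral epithelium (-2.90 without control 10, up to 0.14 without control 5) and ribosomal protein genes (-0.38 without control 5, up to 0.03 without control 6, 0.05 without control 10 and 0.068 without case 5). Lists called in neither fit also changed sign: osteoblast, osteocyte, tooth-forming cell and Wnt genes, with the values given under bone cells, skeletal muscle without case 9 (-0.23), glycolysis without case 5 (0.06), control 6 (0.07) or control 10 (0.01), small non-coding RNA without control 5 (-0.11), 6 (-0.07) or 10 (-0.20) or with at least 10 counts in 3 libraries (-0.10), and histone without control 10 (-0.03). Skeletal muscle also reversed without both number 5 libraries (-0.74), and proliferation, called with all libraries, with the replicate block (-0.019), under which uncalled lists changed sign too (osteoblast 0.07, Wnt 0.04, small non-coding RNA -0.23, histone -0.23). For muscle and epithelium without control 5 the shares of counts in that library account for it, and for the others the cause was not tested. The labels do not say that the shared numbers 5 and 6 pair libraries. Deviations from the group means correlated at 0.38 between case 5 and control 5. Between libraries of different numbers the correlations ran from -0.34 (case 5 and control 6) to 0.28 (case 9 and control 6), with 0.14 for case 6 and control 10. Between case 6 and control 6 the correlation was 0.14. With the number as a replicate block over the 4 libraries numbered 5 and 6, 0 genes and 11 lists passed: of the 17, fibrillar matrix (median -0.06), matrix proteinases (-0.14), endothelium (-0.10), neutrophil (0.06), macrophage (0.16), B and plasma cell (0.07), proliferation and ribosomal protein genes (-0.04) did not, while cartilage (-0.48) and interferon response (-0.32) did. The block fit also has fewer libraries. Of 111 tested genes named by the rule, 99 had the same sign in every alternative and 12 changed sign in at least 1; of 1442 values of a gene under an alternative, 10 passed the threshold, all in DESeq2. The first component held 42.4% of the variance with a prior count of 0.5. Depth and spread limit what could be seen of small changes, since 11.5% of simulated 2-fold changes were called, against 17.7% among genes with a mean count of at least 100. Of simulated 4-fold and 8-fold changes 66.9% and 88.7% were called.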

Other observations

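Lists and genes in this part were chosen after their values were seen, except where stated. Genes of antigen presentation had higher means in the case libraries (source field without corticision) than in the control libraries, none of them past edgeR's adjusted threshold. Ciita, the master regulator of MHC class II genes, was at 46.3 ± 16.4 CPM in case and 19.6 ± 3.57 in control, and Igha, singled out for its value, the heavy chain of immunoglobulin A, at 5220 ± 2400 and 1860 ± 172. All 10 tested members of an MHC class II list, drawn up after Ciita had been seen and holding it, had a positive fold change (median log2 CPM difference 0.51), with a camera p of 5.88e-05 that became 0.21 with an estimated correlation. The libraries overlapped, since the mean log2 CPM of this list was 5.54, 6.71 and 7.15 in case 5, 6 and 9 and 5.93, 6.12 and 5.53 in control 5, 6 and 10. Of 8 tested plasma cell genes that had not been inspected, 2 had a negative fold change and the median was 0.30, with a camera p of 0.105. The adhesion gene Vcam1 was at 156 ± 31.2 and 82.2 ± 16.4 CPM. None of these genes passed edgeR's adjusted threshold, while Ciita and Igha were among the 26 genes of DESeq2.

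Among the 13 genes that DESeq2 called lower in case were Ccl9, Il6, Cxcl3, Mmp12, Hnrnpc, Ier3, Hbb-b1 and Tnfrsf12a, the receptor of the cytokine TWEAK, at 9.2 ± 2.40 CPM in case and 22.9 ± 5.85 in control. Its 13 genes higher in case included Tpsab1, Mcpt1l1, Cd22, Ciita and Igha. Of the 26, 12 are named LOC, and 22 were also tested in edgeR, in all of which the groups lay apart.

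Every test of an explanation or of other splits in this part was chosen only after its pattern had been seen. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For edgeR the real count is 0, which all 10 splits reach by construction, so this count says nothing about chance; the highest other gave 2. For DESeq2 6 gave at least the real 26, the highest other giving 303. For the list test 2 gave 17 lists, the real split among them. The other splits gave 4 to 17 lists, so many calls at the preset correlation also arise when libraries are not split by group. The 4 splits that put case 5 and control 5 on the same side gave 102 to 303 genes in DESeq2. This points to a difference from the other libraries that case 5 and control 5 share, though they lay at opposite ends of the third principal component. The tooth-forming cell list had a higher mean log2 CPM in case 5 (3.72) and control 5 (3.89) than in the others (1.19 to 1.57). Its part in the shared difference was not tested.

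The acute inflammation list was lower in case, with a median of -1.20. Fewer myeloid cells in the case samples would lower the myeloid lists too. Their mean score was higher in case by 0.308 (SE 0.38), less than its standard error, so its direction is unclear. The score pools genes of precursors and of mature cells. It argues against a drop of all myeloid cells near the size of the list's, while a smaller drop, or one of mature cells alone, remains open. Control 5, the library with epithelial genes, is not the source, since the median without it was -1.56. Of the 10 splits only 1, the real one, gave a list p as small as 6.93e-10, the smallest of the others being 7.47e-10, and the splits are too few for a share under 0.05. A difference in inflammatory signalling between the treatments may stand behind the pattern, which was not tested, and the conflict of the labels leaves open which treatment it would go with.

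Control 5 held 27138 counts of the basal keratin gene Krt14, where the others held 20 to 306. Of 14 tested genes of stratified epithelium that had not been inspected, control 5 was the highest library for 11, where equal odds for each library would give 1 in 6 (one-sided exact binomial p = 6.11e-07, with genes that are not independent). How often control 5 is the highest library over all genes was not counted, so this p may be too small. The osteoblast score of control 5, 8.54, lay within that of the others, the lowest of which was 8.44, which argues against a library of another tissue. Epithelium, such as gum, taken along with the bone may be the source. No biological explanation was tested, since the pattern is in 1 library.

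Mast cell genes were higher in case, with a mean difference of 0.70 over 13 genes, some of them chosen for it. Beside Tpsab1 stood Cpa3 (9.96 ± 4.71 against 3.83 ± 0.256 CPM) and Tpsb2 (6.53 ± 3.65 against 2.37 ± 0.590 CPM). A test of that list itself would only restate what it was chosen for. If the case samples held more mast cells, mast cell genes that had not been inspected should move alike, and 7 such genes, 5 of them also among the 13, had a median difference of 0.27 (SE 0.16 over genes), with 4 positive and 3 negative fold changes, separate groups in 1 and a camera p of 0.0346 (p = 0.2 with an estimated correlation). That is below the difference the test required, but by less than 2 standard errors. The required difference was set from the mean over the 13 genes, whose median was lower at 0.46. The shortfall thus depends on setting a median against a mean. More mast cells and a higher output of proteases per cell therefore cannot be told apart, and a difference in where the samples were cut may also play a part, which was not tested.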
